A study of Mus musculus with 2 samples.

How the data were processed

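Testes of 8-month-old mice were measured by 10x Genomics single-cell RNA sequencing, with 1 library from wild type and 1 library from the Igf2bp1 conditional knockout. The number of animals behind each library cannot be read from the labels without doubt, so each library counts as 1 replicate. The Cre line and the deleted exons are not given in the sources used here. Per the labels' protocols, the tissue was digested in consecutive enzyme steps, strained, loaded on a droplet chip and sequenced, and the matrix came from Cell Ranger. Per the submitters' processing notes, the tools were Cell Ranger 2.2.0 and STAR and the genome build was mm10, while per the file headers the matrices carry software version 3.1.0. The deposited matrices hold raw UMI counts per gene and barcode, per the file headers and from the values, which are whole numbers. How the authors called barcodes as cells is not given in the sources used here.

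The wild type library has 17362 barcodes and 121257944 UMIs, with a median of 1242 UMIs and 843 genes per barcode. The knockout library has 17968 barcodes and 98033324 UMIs, with a median of 2097 UMIs and 1275 genes. The lowest barcode holds 943 UMIs in wild type and 1246 in the knockout, so shares below compare libraries with different floors. Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs. This left 17002 wild type and 17703 knockout barcodes, and all 360 and 265 removed barcodes were over the mitochondrial limit. Scrublet (scanpy 1.11.5, expected rate 8%) called 0 wild type and 1 knockout barcode, which was taken as not having worked, and no barcode was removed as a doublet.

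Both libraries were clustered together. Counts were scaled to 10000 UMIs per cell and log transformed, 2000 variable genes were chosen within library, and 30 principal components were computed. A shared neighbour graph with 15 neighbours was partitioned by Leiden (leidenalg 0.10.2, igraph 0.11.9) at resolution 1. Clusters were named from fixed markers of 17 cell classes, and a name means only that the cells are like that class. The numeric limits for naming were set after seeing the data. A cluster was left unnamed as empty-like when its median UMIs were under 1.5 times those of the lowest decile of barcodes and no class's markers rose by 1 on the log2 scale over that background. It was left unnamed as mixed in any of 3 cases: its best class was somatic but its protamine and transition protein UMIs were over 3 times that background, its 10 leading genes fell under a 2-fold lead, or another class had more markers among them. Unnamed clusters hold 62.7% (empty-like) and 2.2% (mixed) of kept wild type barcodes, against 42.5% and 32.4% of knockout barcodes, with 672 and 680 further barcodes unnamed for few UMIs. The cluster that held spermatogonia and early spermatocytes was clustered again to tell them apart. A cluster mostly of 1 library may be that library and not a cell type.

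Shares carry exact Clopper-Pearson 95% intervals. A share of 0 is given with the limit that 3 counts would set. For each class with at least 50 cells in each library, raw UMIs were summed per library and given as CPM, the gene's share of all UMIs of the class scaled per 1e6, with exact Poisson intervals. The knockout over wild type ratio has an exact conditional binomial 95% interval (scipy 1.17.1). With 1 library per genotype no p-value is given. All intervals and floors cover counting error only, not variation between animals. A gene is called higher or lower only when its ratio is at least 1.5-fold and the interval leaves out 1. For 27 gene lists fixed before the data were examined, the median log2 ratio of members with at least 20 UMIs was placed among 10000 random lists of matched expression (20 bins). That percentile describes these 2 libraries, not the genotypes. A list was read only in classes where at least 3 members were measured.

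Genes are named by a fixed rule. It takes Igf2bp1, Igf2bp2 and Igf2bp3, and per class the 10 highest and 10 lowest ratios ranked by the interval bound nearest to 0. It asks for at least 50 UMIs and a class level of at least 0.5 times that of all kept cells of that library. Numbered gene models, haemoglobin, mitochondrially encoded and ribosomal protein genes are left out of the ranking. The rule adds up to 4 members per list with the largest bounds, and the cell type markers. For elongating spermatids only the first 5 each way may be named. Results for some ranked genes are not reported here. Free RNA was read from the lowest decile of barcodes by UMIs in each library. An alternative instead took off 5% of a class's UMIs by the profile of all kept barcodes, Leydig cells included.

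Simulated counts with known answers were drawn from each class and run through the same code. Of 200 changed genes per class, 100 were changed 2-fold and 100 4-fold. The 2-fold changes were recovered in 86% to 95%, and the intervals of unchanged genes held a ratio of 1 in 95.4% to 96.1%. Class sums were drawn as Poisson counts with no spread between cells, so these intervals hold by construction. Genes carried by few cells are not covered. A simulated list of 20 genes raised 1.5-fold lay at percentile 100 in every class compared, and 1 of unchanged genes at 52.3 to 80 in 4 classes but at 99.45 in elongating spermatids, so percentiles there can be high with no change. Alternatives were tried for the barcode filter, doublets, resolution, joint clustering, cluster names, depth, scaling (edgeR 4.0.16 TMM in R 4.3.3, and median-of-ratios factors), the low-count filter, the mix of clusters and free RNA. Positions are from the GENCODE annotation of the same build. Sums used numpy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9, in python 3.11.15.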

Results

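The question behind the libraries is what the loss of IGF2BP1, a protein that binds mRNAs and is known for keeping some of them stable and translated, does to the aged testis. Each comparison sets the knockout library against the wild type library at 8 months of age. Cell classes are named by markers, so spermatogonia below means spermatogonia-like cells, and so on for every class.

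Igf2bp1 itself was lower in knockout spermatogonia. In wild type its transcripts were densest in spermatogonia, the dividing cells from which sperm production starts. There the level dropped from 70.8 CPM (95% interval 55.4 to 89.2; 72 UMIs) to 23.4 CPM (13.4 to 38.0; 16 UMIs), a log2 ratio of −1.60 (−2.48 to −0.80). A transcript was found in 44 of 122 wild type cells (36.1%) and in 14 of 83 knockout cells (16.9%), at median depths of 8081.5 and 7043 UMIs. Empty-like barcodes, which should lack the gene, held it in 0.376% and 0.399% at median depths of 1107 and 1463 UMIs, with levels of 3.21 and 2.58 CPM. The remaining knockout transcripts are therefore above the free RNA. The deleted exons are not given, so 3′ tags of a truncated transcript can still be counted, and cells that escaped deletion cannot be told from such tags. Wild type and knockout spermatogonia lie mostly in different sub-clusters (77 of 122 wild type cells in sub-cluster 0, 52 of 83 knockout cells in sub-cluster 1). The gene was lower in both: 73.7 against 35.4 CPM in sub-cluster 0, and 62.7 against 13.4 CPM in sub-cluster 1. Early spermatocytes had 6 and 2 UMIs, too few to compare. Round spermatids had 122 and 26 UMIs and no clear drop, with a log2 ratio of −0.37 (−1.04 to 0.25). Free RNA was estimated at 3.31% and 6.32% of their UMIs. Their level is therefore more than free RNA would give, though close to that of empty-like barcodes. Late spermatocytes, round and elongating spermatids together stood at −0.57 (−1.14 to −0.03), under the 1.5-fold limit. Of its paralogs, Igf2bp3 held 43.3 and 41.0 CPM in spermatogonia, below its level over all cells. Igf2bp2 had 10 UMIs in wild type and 0 in the knockout. With the knockout set to a floor of 3 counts it was 2.24-fold lower (upper 95% limit of the log2 ratio −0.59).

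**Figure D1:**
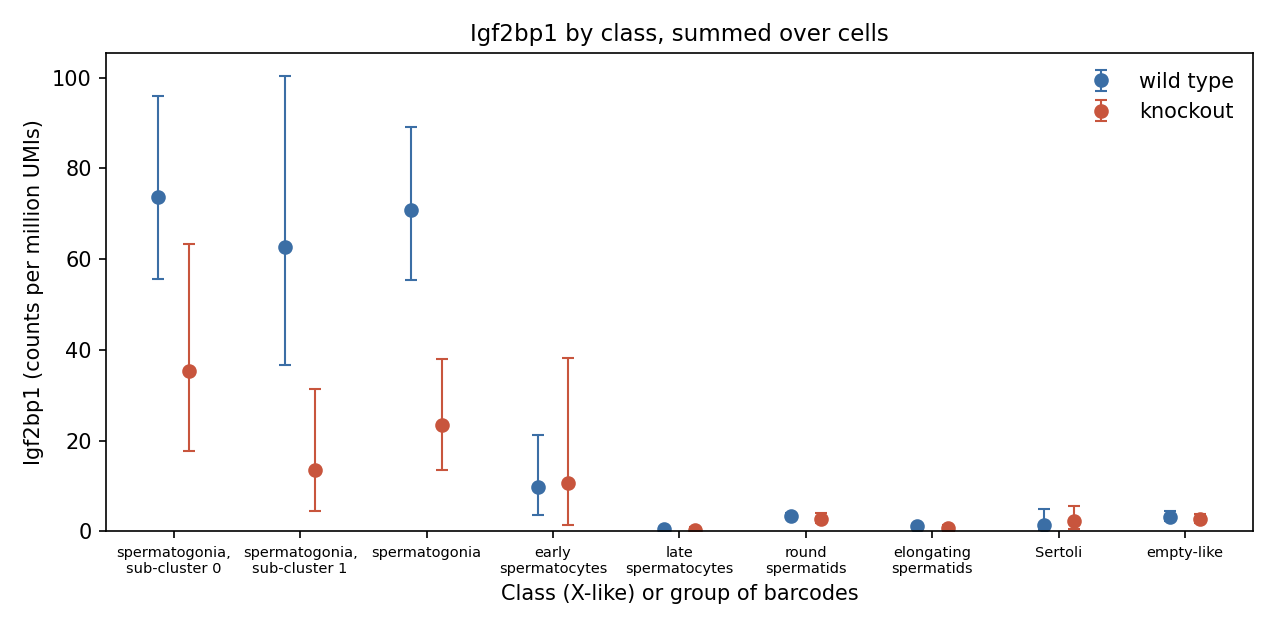
Level of Igf2bp1 (CPM of summed UMIs, vertical axis) by class and in empty-like barcodes, for the wild type and knockout libraries; points are levels and bars exact Poisson 95% intervals. Wild type spermatogonia stand at 70.8 CPM and knockout spermatogonia at 23.4 CPM. Round spermatids stand at 3.45 and 2.68 CPM, late spermatocytes at 0.518 and 0.157 CPM and empty-like barcodes at 3.21 and 2.58 CPM. Free RNA is only a part of the UMIs of a germ class, so the empty-like level is not a floor for these classes.

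The make-up of the libraries differed widely. Germ cells were 83.5% (82.4 to 84.5) of named wild type cells and 46.7% (45.1 to 48.3) of named knockout cells, a log2 ratio of −0.84 (−0.92 to −0.76). The somatic classes were larger in the knockout in turn. Sertoli cells, which nurse the germ cells inside the tubules, went from 14.4% (13.4 to 15.3) to 24.1% (22.7 to 25.5) of named cells. Leydig cells, which make testosterone between the tubules, went from 0.811% (0.587 to 1.09) to 9.84% (8.91 to 10.8), or from 43 to 370 cells. Macrophages went from 43 to 195 cells (log2 2.68), T or NK lymphocytes from 4 to 124, and mesenchymal cells of the interstitium from 25 to 61. B lymphocytes were 349 in the knockout (9.28%) and 0 in wild type, which allows a share of up to 0.0566%. Among somatic cells alone, Leydig cells were 4.90% and 18.5% and Sertoli cells 86.9% and 45.2%. These shares rest on the named cells, 31.2% of kept barcodes in wild type and 21.2% in the knockout. A further 5742 knockout barcodes were left unnamed as mixed, against 374 in wild type. Most of the knockout ones lie in clusters set apart for protamine UMIs over 3 times the free RNA, though these clusters are also deeper. The largest such cluster, led by the Leydig genes Insl3, Cyp11a1 and Cyp17a1, has 24 wild type and 3407 knockout barcodes, so the shares depend on how these are counted. With mixed clusters named by their best class the log2 ratio of the Sertoli share goes from 0.74 to 0.02, that of germ cells from −0.84 to −1.71 and that of Leydig cells from 3.60 to 5.15, the last with 473 knockout barcodes led by myoid genes counted as Leydig. With each cell named by its marker level they are 0.13, −1.24 and 4.46.

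**Figure D2:**
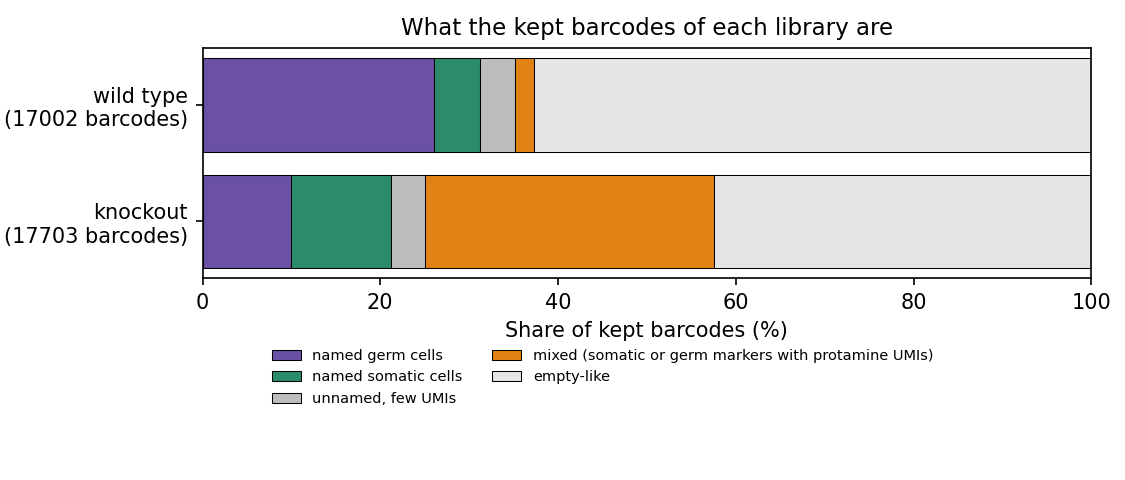
Share of kept barcodes (%, horizontal axis) that were named as germ or somatic cells, had few UMIs, were mixed or were empty-like, in the wild type and knockout libraries. Mixed barcodes are 2.2% in wild type and 32.4% in the knockout, and empty-like barcodes 62.7% and 42.5%.

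Within the germ line, every stage from spermatogonia to elongating spermatids was present in the knockout. Spermatogonia were a larger part of the germ cells, 4.73% (3.78 to 5.83) against 2.76% (2.29 to 3.28), a log2 ratio of 0.78 (0.36 to 1.19). That gap is under 1.5-fold with the stricter barcode filter (59 of 1776 germ cells against 114 of 4460), with cells thinned to 1000 UMIs (75 of 1961 against 123 of 4562) and with mixed clusters named by their best class (83 of 2409 against 122 of 4668). Late spermatocytes, the cells at the pachytene stage and the meiotic divisions, were 19.6% (17.8 to 21.5) against 26.0% (24.8 to 27.4), a log2 ratio of −0.41 (−0.59 to −0.24), under the 1.5-fold limit, and this ratio turns to 0.47 with mixed clusters named by their best class. Early spermatocytes were 2.05% and 2.01%, round spermatids 27.0% and 27.3%, and elongating spermatids 46.7% and 41.9% (log2 0.16, 0.03 to 0.27). The ratio of elongating spermatids turns to −0.21 with mixed clusters named and to −0.15 with each cell named by its marker level. Of the elongating cells, 215 in wild type and 42 in the knockout come from a cluster of few UMIs (medians 1631 and 1977.5) whose protamine UMIs are near the free RNA. Spermatogonia together with early spermatocytes were 6.78% of germ cells against 4.77% (log2 0.51, 0.17 to 0.84). Wild type named cells were deeper (median 16062 UMIs against 4838), with a smaller gap within late spermatocytes (19406 against 14725).

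**Figure D3:**
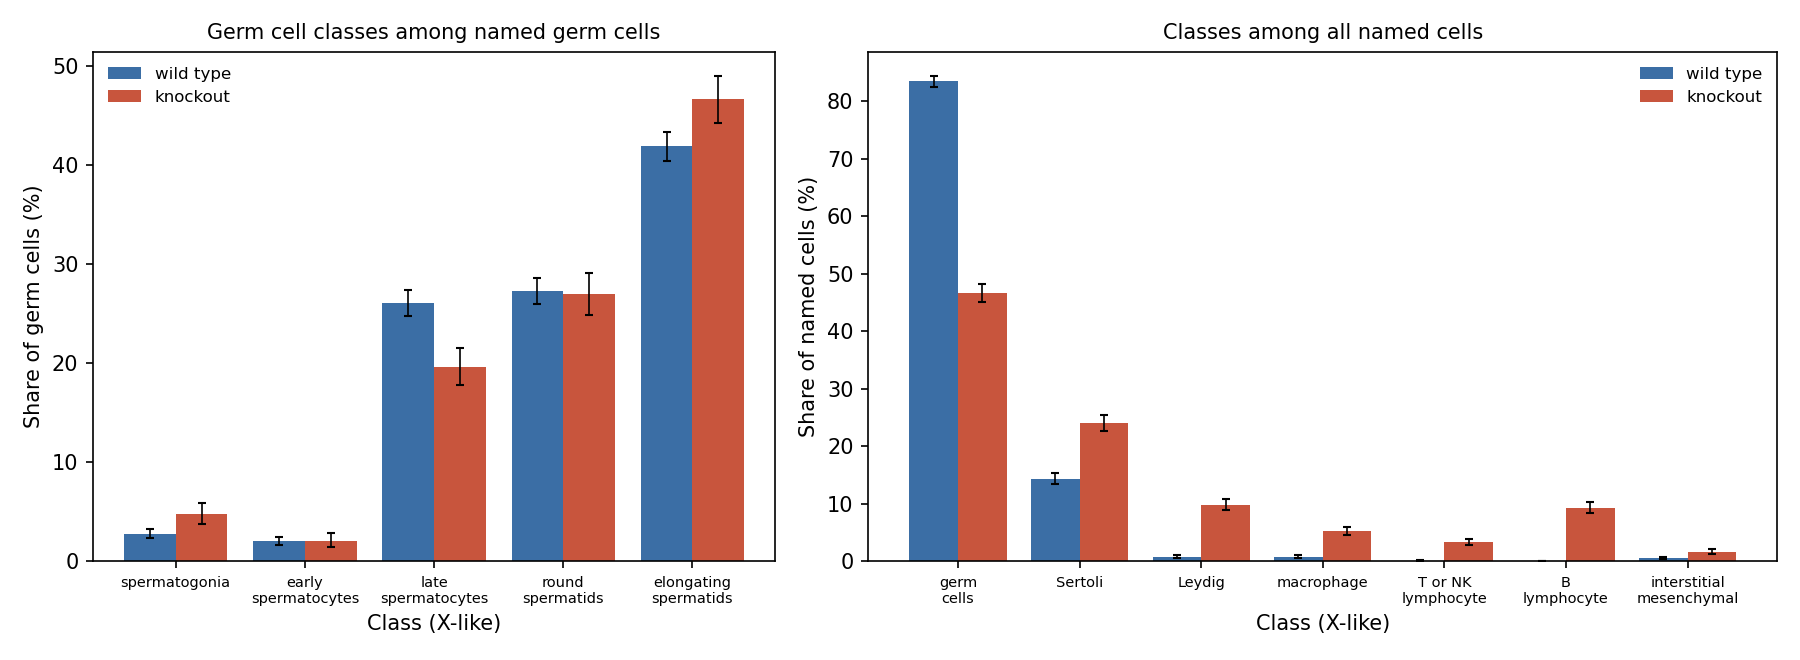
Share (%, vertical axis) of each germ cell class among named germ cells and of each broad class among all named cells, with exact Clopper-Pearson 95% intervals as bars on the columns; wild type and knockout are 1 library each. Germ cells are 83.5% and 46.7% of named cells, while round spermatids are 27.3% and 27.0% of germ cells.

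In spermatogonia, 3 genes of the stem and early differentiating state were lower in the knockout, while most measured members of these lists did not pass the limit. Of 4740 genes that met the filters of the naming rule outside a stretch of chromosome 16, 340 (7.17%) passed the same limit. The mix of sub-clusters also differs between the libraries. Lin28a, an RNA-binding protein of undifferentiated and early differentiating spermatogonia, dropped from 32.5 to 8.78 CPM (log2 −1.89, −3.43 to −0.61; 33 and 6 UMIs). Kit, the receptor that drives differentiation, dropped from 104 to 62.9 CPM (log2 −0.73, −1.27 to −0.20), and Dnmt3b, a DNA methyltransferase of the same step, from 76.7 to 36.6 CPM (log2 −1.07). Rest, a repressor of neuronal genes, dropped from 159 to 77.6 CPM (log2 −1.04, −1.51 to −0.58). Rpa3, a part of the complex that coats single-stranded DNA during replication and repair, dropped from 51.1 to 11.7 CPM (log2 −2.13, −3.41 to −1.04) and was seen in 40 wild type and 8 knockout cells. Rising genes were led by Lepr, the leptin receptor, from 30.5 to 117 CPM (log2 1.94, 1.33 to 2.59; 32.5% of its knockout UMIs in 1 cell, and 0.84 under the stricter barcode filter). They also include Malat1, a nuclear non-coding RNA, from 2204 to 3420 CPM (log2 0.63, 0.55 to 0.72), Brsk2, a kinase of cell polarity (log2 1.61), and Il11, a cytokine (log2 0.74).

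By list, 1 of 7 measured stem cell maintenance genes was lower (Lin28a) and none higher, with a median of −0.43 at percentile 2.35. That median rests on the mix of sub-clusters: with equal weights its excess over matched lists turns from −0.42 to 0.04. Of 14 differentiation and retinoic acid genes, 2 were lower (Kit, Dnmt3b) and none higher (median −0.23, percentile 1.28). Of 12 meiotic recombination genes, Brca1 was lower (log2 −0.72, −1.39 to −0.08) and none higher, with a median of −0.39 at percentile 0.09, and Tex15 stood at −0.29. Of 17 piRNA pathway genes, which silence transposons, 3 were lower: Asz1 (−1.34), Tdrd7 (−1.43) and Tdrd12 (−1.26), with a median of −0.14 at percentile 10.9. Of the 12 measured synaptonemal complex genes, Tex12 was lower (−1.21) and Sycp2 higher (0.64, 0.00 to 1.28), with a median of 0.02. The 25 cell cycle genes had a median of −0.01, with Ccne2 higher (0.83) and Bub1 lower (−1.09), and Mki67 at 0.36. Of 19 genes of the IGF2BP family and m6A machinery only Igf2bp1 was lower (median −0.08), Hnrnpa2b1 standing at −0.41. None of 11 mRNAs described elsewhere as bound by IGF2BP1 was higher or lower (median −0.13, percentile 25.7). The 23 ribosomal protein genes had a median of −0.16 at percentile 0.97, with none past the limit (Rpl5 −0.43). Of 11 apoptosis genes 1 was higher and 1 lower (median −0.03), and of 18 DNA damage signalling genes 2 were lower and none higher (median −0.10, percentile 17.9). Acrosome and flagellum genes, which belong to spermatids, had medians of 0.35 and 0.35 (percentiles 99.97 and 99.98). Only 3 of 20 acrosome members reached 0.5 times their all-cell level in this class. Free RNA was estimated at 11.6% of wild type and 15.8% of knockout UMIs here. Other genes ranked by the rule rest on few cells. Removing the cell with most UMIs turns Afg3l1 from 1.48 to −0.22, Mirt1 from 1.09 to −1.17, Gfod2 from 1.34 to −0.05 and Ppm1k from −2.98 to 2.57, and Olfr655 (−1.33) was seen in 12 and 3 cells. Further ranked genes are Slc6a21 (1.07), Synrg (1.26) and Hist1h2aa (1.24), which were higher, and Ttf1 (−1.72), Mef2b (−1.61), Gnb4 (−1.68) and Dst (−1.45), which were lower.

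**Figure D4:**
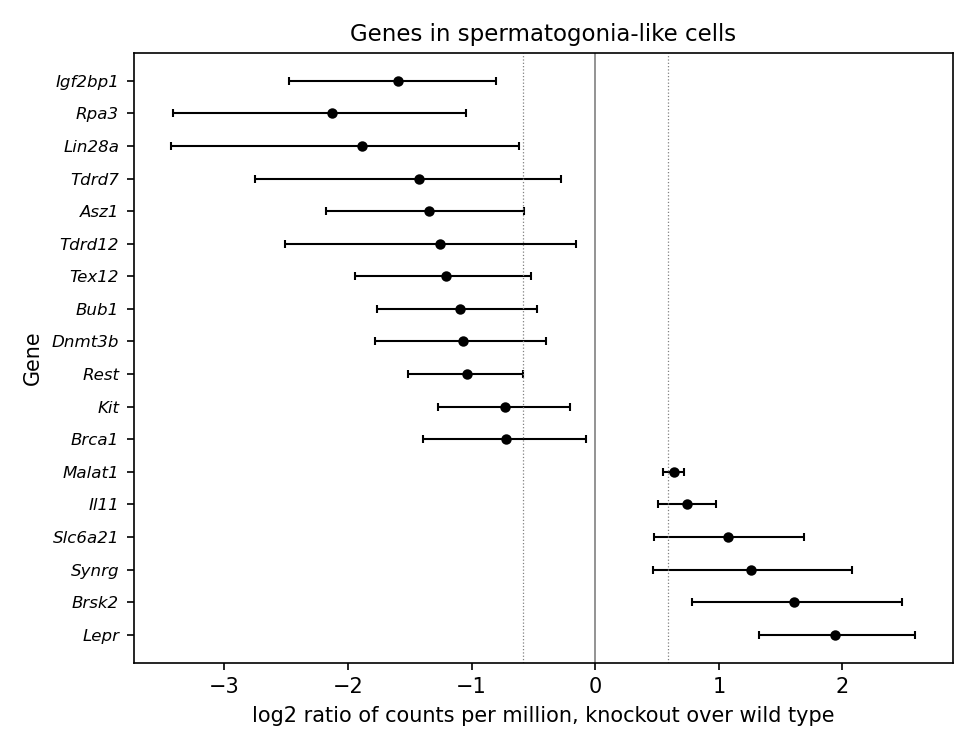
Log2 ratio of CPM, knockout over wild type (horizontal axis), for named genes in spermatogonia; points are ratios of summed UMIs, bars exact conditional binomial 95% intervals, and dotted lines mark 1.5-fold. Igf2bp1 lies at −1.60, Rpa3 at −2.13 and Lepr at 1.94.

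In late spermatocytes the meiotic programme itself stood close between the libraries. Of 19 recombination genes 2 were lower: Spo11, which makes the breaks that start recombination (log2 −0.61, −0.83 to −0.39), and Tex15 (−0.64), which is below its all-cell level here. The median of that list was 0.01. None of 18 piRNA genes passed the limit (median 0.04), Piwil1 standing at 0.38 (329 and 429 CPM). Acr, the protease of the acrosome, stood at −0.42 and Pcna, the replication clamp, at −0.34. Lower genes include Lpcat4, a phospholipid enzyme, from 9.18 to 1.57 CPM (log2 −2.55, −3.62 to −1.65), and Jam2, a junction adhesion molecule, from 27.1 to 11.5 CPM (log2 −1.24, −1.61 to −0.89). Epcam, an epithelial adhesion molecule, dropped from 58.1 to 30.2 CPM (log2 −0.94). Fmnl1 (−1.33), Dact2 (−1.48), Dynlt1b (−1.06), Rgs9 (−1.24), Hist2h2aa1 (−0.88) and P4ha2 (−1.69) were lower too, and Olfr183 had 91 UMIs against 1 (−4.32, −9.64 to −1.81). The junction gene Cldn3 was lower as well (−1.05, −1.96 to −0.25). Higher genes were mostly of low level: Shprh (1.39), Spint5 (1.25), Mpp7 (1.29), Svopl (1.46), Sun2 (1.35), Surf6 (1.11), N6amt1 (0.98) and Nup93 (1.04). The unnamed locus AC113204.1 rose from 68.2 to 131.9 CPM (log2 0.95, 0.83 to 1.07). Ptcra (2.12) has 68.2% of its knockout UMIs in 1 cell. Ccne2 was higher here as well (0.69, 0.46 to 0.92). The 27 flagellum genes had a median of −0.08 at percentile 1.62 with none past the limit. The 23 ribosomal protein genes had a median of 0.18 at percentile 100, with 2 higher and none lower.

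In round spermatids, the class in which the acrosome and tail are built, those programmes differed by little. None of 20 acrosome genes and none of 27 flagellum genes passed the limit, with medians of −0.08 (percentile 0.340) and −0.08 (percentile 1.34). Acr stood at −0.46, Spaca1 at −0.29 and Catsper2 at −0.30, all with narrow intervals. Chromatin compaction genes had a median of −0.05, and Tnp1 stood at −0.21, a value that turns to 0.19 when the clusters of the class weigh equally. Single genes moved further. Tmed6, a vesicle transport protein, dropped from 37.9 to 13.6 CPM (log2 −1.48, −1.75 to −1.22), Hist2h2aa1, a histone gene, from 202 to 105 CPM (−0.95) and Jam2 from 24.7 to 11.7 CPM (−1.07). Tmem198 (−2.53), Sost (−1.38), Olfr183 (−1.30), Dynlt1b (−0.96), AC154242.1 (−1.42) and AC122551.1 (−1.02) were lower too, and BC028528 (−4.29) has 39.4% of its wild type UMIs in 1 cell. App, the amyloid precursor protein, rose from 70.2 to 121 CPM (log2 0.78, 0.68 to 0.88). Acer2, a ceramidase, rose from 7.83 to 17.1 CPM (1.13), and AC113204.1 (1.04), AC135964.2 (2.19), AC154719.1 (1.14), Cngb1 (1.30), Col4a4 (1.41), Dnah5 (1.36) and Dnase1l3 (1.11) were higher.

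In elongating spermatids, scaling shifts all genes: TMM and median-of-ratios factors would lower every knockout ratio by 0.23 and 0.25, and the median gene stands at 0.19, so values here are read against that shift. Genes for proteins that pack sperm DNA and for sperm glycolysis had medians close to those of matched random lists (0.02 and 0.05). Acrosome and flagellum genes had medians above their random lists, each at 0.14 (0.29 at percentile 99.54 with 1 of 20 higher, and 0.26 at percentile 98.35 with 3 of 27 higher, none lower in either). Only 3 of 20 and 7 of 27 members reached 0.5 times their all-cell level. Both excesses turn with 1 lowest-decile barcode subtracted per cell (−0.014 and −0.11). That of flagellum genes also turns with equal weights of clusters (−0.017). The 16 measured compaction genes had a median of −0.02 (percentile 24.6) and the 14 sperm glycolysis genes 0.00 (percentile 25.2), with none past the limit. Gapdhs, the sperm form of a glycolytic enzyme, stood at −0.31, Akap4, which anchors kinases in the tail sheath, at −0.25 and the histone variant H2al2a at −0.22. Tnp2 stood at 0.19, and at −0.04 and −0.07 with the other scalings. Lower genes were Tmem239, from 180.3 to 93.1 CPM (log2 −0.95, −1.05 to −0.86), Eva1c (−0.81) and Upk3bl (−0.69). Myo15b (−1.36) turns to 0.58 with equal weights of clusters. Higher genes were Shank2, a scaffold protein, from 73.7 to 124 CPM (0.75, 0.65 to 0.85; 0.52 and 0.50 with the other scalings, under the limit), Rb1 (1.32), Plagl2 (1.21) and AC164425.1 (1.19). The mRNAs described as bound by IGF2BP1 had a median of 0.05 here (11 measured), −0.07 in round spermatids (12) and −0.06 in late spermatocytes (11), with none past the limit in these 3 classes. In Sertoli cells 2 of 7 were lower and none higher (median −0.32, percentile 4.94). Igf2bp1 itself had only 2 and 4 UMIs there, at 1.35 and 2.16 CPM against 3.21 and 2.58 CPM in empty-like barcodes (wild type and knockout).

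Sertoli cells carry few UMIs (medians 1317 and 1708), of which free RNA was estimated at 49.7% in wild type and 63.5% in the knockout. Their own genes gave no common direction. Of 12 support genes, Shbg, the androgen-binding globulin, was higher (1.11, 0.02 to 2.33) and Wt1, a transcription factor of Sertoli identity, lower (−0.66, −1.33 to −0.01), while Inha stood at 0.27 (median 0.03). The 17 barrier and junction genes had a median of −0.13. Creg1, a secreted glycoprotein far above its all-cell level, dropped from 88.3 to 39.5 CPM (−1.16, −1.60 to −0.74), and Igfbp7 from 74.1 to 38.9 CPM (−0.93). Tnni3 rose from 28.3 to 71.9 CPM (1.34, 0.83 to 1.88) and Dstn, an actin severing protein, from 111 to 200 CPM (0.85). The glutathione transferase genes Gstm1 (1.03) and Gsta3 (1.71), Ptms (1.82) and Ctsb (1.56) were higher at about 0.5 times their all-cell level. Akap14, Tceal9, Actl11 and Spata21 were higher, and Sdf2l1, Crtam, Dynlt1b, Tcte3, Emc7, Pabpc6, Rsph3a, Mgat4d and Ppp1r27 lower, each near the level of free RNA.

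Across classes, Leydig transcripts and immediate early genes were higher in knockout germ cells. Insl3, the Leydig hormone, was higher by 3.57 in spermatogonia, 3.14 in late spermatocytes, 2.90 in round and 3.46 in elongating spermatids on the log2 scale. Its level in these classes is at most 0.067 times its all-cell level. Taking off 5% of the profile of all kept barcodes turns Insl3 to −1.37 in late spermatocytes and −2.84 in round spermatids. That profile holds the Leydig cells and Leydig-led barcodes, with Insl3 at 129 and 1924 CPM (wild type and knockout). It may therefore take off more than free RNA. Cyp17a1, an enzyme of testosterone synthesis, was higher by 4.34, 4.62 and 4.92 in the 3 later classes, and by 3.50 in Sertoli cells. Of the measured steroidogenesis genes, 8 of 15, 8 of 16 and 9 of 15 were higher and none lower in late spermatocytes, round and elongating spermatids, and 7 of 12 in Sertoli cells. Of the immediate early and dissociation stress genes, 12 of 16, 12 of 18, 11 of 16 and 8 of 14 were higher in those classes, Fos by 3.54, 2.30, 3.46 and 4.33. In spermatogonia 4 of 13 were higher, Fos by 0.99 and Zfp36 by 1.90. In Sertoli cells the list's excess of 1.92 turns to −0.47 once the lowest-decile barcodes are subtracted. Other lists of somatic genes rose in late spermatocytes, round and elongating spermatids too. Of phagocytosis and lysosome genes 4 of 13, 6 of 12 and 5 of 10 were higher there, and of Sertoli support genes 2 of 7, 5 of 10 and 3 of 5, none lower. Barrier and junction genes did not follow in late spermatocytes (1 of 18 higher, 3 lower) or round spermatids (1 of 17 higher, 1 lower), but 4 of 13 were higher in elongating spermatids. Interferon response genes, most abundant in immune and interstitial cells, were higher for 7 of 7 members in elongating spermatids (median 1.39), 4 of 8 in round spermatids (0.63), 2 of 7 in late spermatocytes (0.40) and 2 of 4 in Sertoli cells (1.14), while in spermatogonia none of 4 was higher and 1 lower (−0.15). Mitochondrially encoded genes followed in the later classes: 7 of 13 were higher in elongating spermatids (median 0.59, mt-Co1 0.67) and 2 of 13 in round spermatids (median 0.40, mt-Nd2 0.69), with a median of 0.22 in late spermatocytes. In elongating spermatids TMM or median-of-ratios factors would lower each ratio by 0.23 or 0.25. That takes mt-Co1 and this list's median under the 1.5-fold limit, and the counts given for that class are before this shift. None of the 13 in round or elongating spermatids, and none of the 7 interferon genes in elongating spermatids, reached 0.5 times its all-cell level. Free RNA was estimated at 3.85% and 7.02% of UMIs in late spermatocytes, 3.31% and 6.32% in round and 6.5% and 9.42% in elongating spermatids (wild type and knockout).

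**Figure D5:**
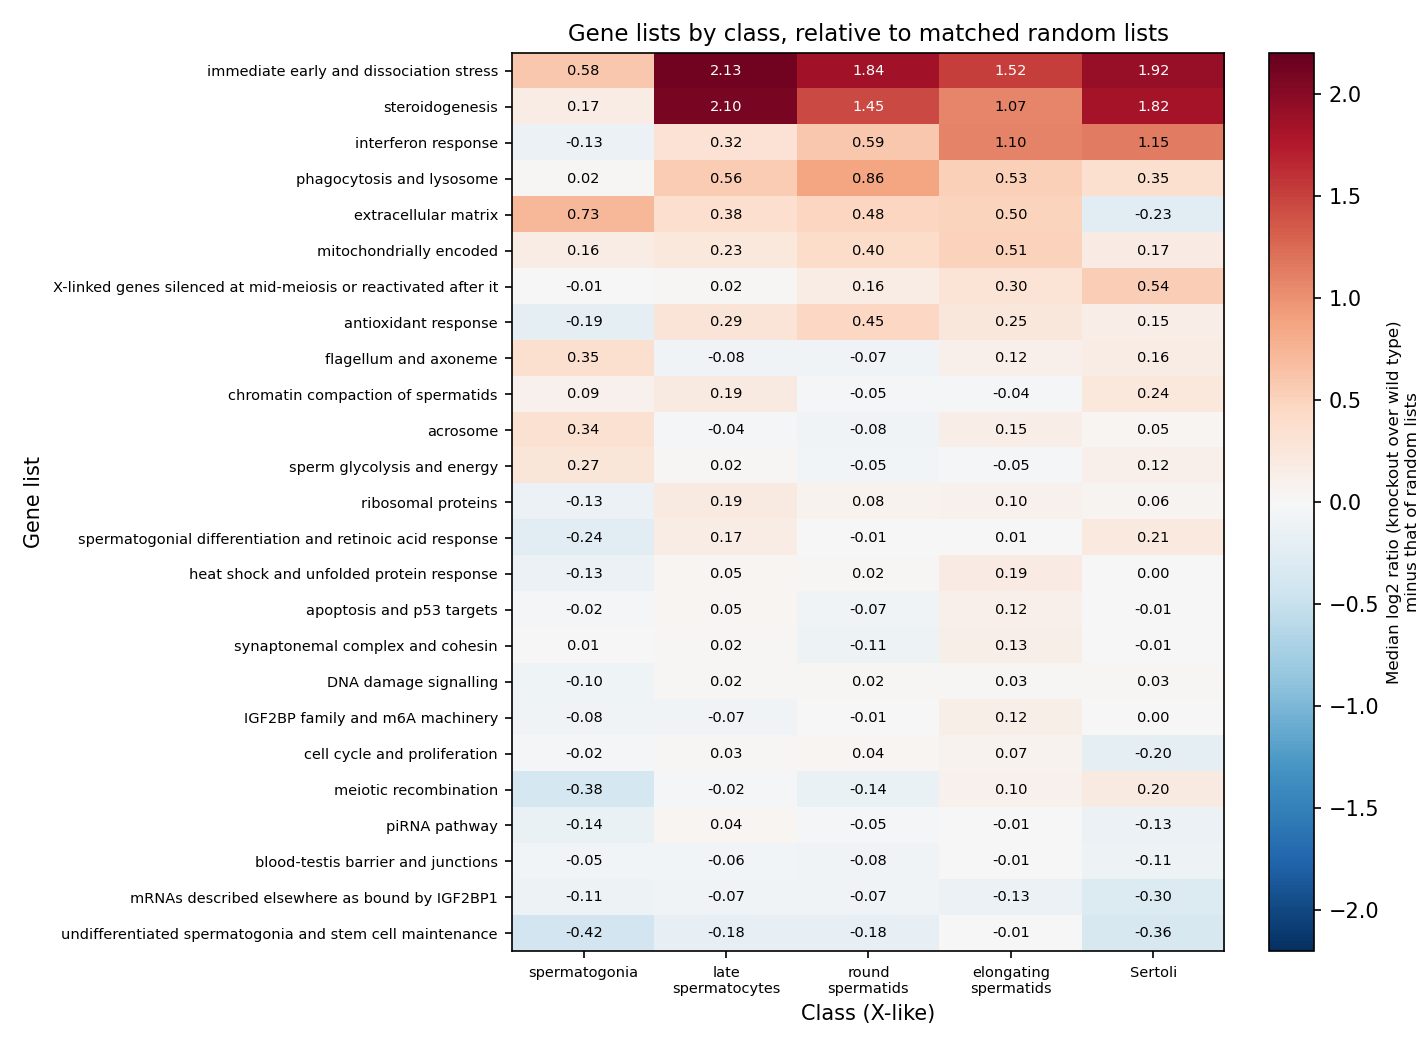
Median log2 ratio of each gene list minus that of matched random lists (colour and printed value) by class, knockout over wild type. Immediate early and steroidogenesis lists are highest in late spermatocytes (2.13 and 2.10), while recombination genes in spermatogonia lie at −0.38 and acrosome genes in round spermatids at −0.08.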

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

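The tests on pairs with whole Leydig cells and on the stretch of chromosome 16 were chosen after the results they measure were seen, and the other tests were written down before theirs. Of 3 tests tried on pairs, 2 (on protamine UMIs and on total UMIs) could not decide because of how the barcodes and limits were picked, and only the third is used.

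Marveld3, which encodes a tight junction protein, went opposite ways in neighbouring germ classes: higher in knockout round spermatids (log2 1.32, 0.54 to 2.07) and lower in knockout late spermatocytes (−2.43, −5.51 to −0.50). The gap is 3.74 on the log2 scale. The difference was not tested, since each genotype has 1 library, and the gene was noticed after values were seen.

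Some barcodes outside the named cells hold RNA of many classes at once, and these mixed barcodes are 32.4% of kept knockout barcodes against 2.2% in wild type. Clusters led by Leydig genes (3407 knockout barcodes), myoid genes (473), Sertoli genes (417), macrophage genes (388) and endothelial genes (237) were set apart by their protamine and transition protein UMIs. That 4705 of 5707 mixed knockout barcodes hold over 183 such UMIs, 3 times the free RNA, largely restates the naming rule. The rule ignores depth: in the Leydig-led cluster these UMIs are 6.75 times the lowest decile and all UMIs 5.26 times. The 5707 also hold clusters closest to late spermatocytes (627), B lymphocytes (131) and elongating spermatids (27). Over all 5707 barcodes pooled, free RNA at a higher load as the whole source is argued against. Round spermatid markers are 5.32% of germ marker UMIs in these barcodes and 9.24% in the lowest decile of barcodes, a 1.74-fold gap. Late spermatocyte and elongating markers stand at 0.846 and 1.05 times their share there. The pool holds the clusters closest to germ classes, so this does not decide for the somatic-led clusters. Pairs with a whole Leydig cell are argued against as the source of the Leydig-led cluster: 85.1% (83.9 to 86.3) of its 3407 knockout barcodes hold fewer Leydig marker UMIs than the 10th percentile of knockout Leydig cells, with medians of 31 and 214 UMIs. Pairs of whole cells in the other clusters, somatic cells that carry spermatid fragments, clumps that broke up in the droplets, and an effect of the knockout on the tissue may each be behind it, and none of these was tested.

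B lymphocytes were looked for only as a marker class, yet they are 1.97% of kept knockout barcodes (349) and 0 of 17002 in wild type, which allows a share of up to 0.0176%. No test bears on whether they come from the testis, its vessels or blood left at dissection, and with 1 library per genotype they cannot be ascribed to the knockout.

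Leydig and immediate early transcripts were higher in the knockout in late spermatocytes, round and elongating spermatids, with a median log2 ratio of 1.87 over 96 values. Each value is a list member in 1 class, so genes of the lists of 19 and 20 can count once per class. Subtracting free RNA at the level of 1 lowest-decile barcode per cell leaves a median of 1.41 (quartiles 0.163 and 3.08), but this test cannot decide. What was left of a gene counted as at least 3 counts in each library, and the totals of these classes are smaller in the knockout. A gene removed whole in both libraries therefore still stands as higher in the knockout. Doublets with a Leydig cell are argued against. The 5% of germ cells with most Leydig marker UMIs hold 21.1% of them, close to the 19.8% that even spreading by depth gives. At least 1 such UMI is found in 82.5% of cells. Free RNA at a higher load may still be the source, and for immediate early genes at that load too. Leydig markers are at 119 and 729 CPM in the lowest decile of barcodes of wild type and knockout. In later germ cells they are at 17.6 and 138 CPM. A lowest-decile barcode per cell makes up at most 9.42% of knockout UMIs in these classes (elongating spermatids). At 729 CPM that load falls short of 138 CPM. This argues against it as the whole source of the Leydig markers in this library. Taking off 5% of the all-cell profile turns Insl3 to −1.37 in late spermatocytes, though it leaves Cyp17a1 at 3.50 and Fos at 3.21 there. That profile includes Leydig cells, so this may take off more than free RNA. A response of the germ cells to the knockout and swapped barcodes were not tested.

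App and Rb1 (higher) and Eva1c, Epcam and Nme2 (lower) stood at least 1.5-fold apart the same way in 3 germ classes, with intervals that leave out a ratio of 1 (TMM or median-of-ratios factors would take App, at 0.73 in elongating spermatids, under the limit there), which could reflect a sequence difference between the mice as well as the knockout. A stretch of another strain around Igf2bp1 cannot be told apart from chance with so few genes. Of the 5, 1 (Nme2, 20%, 0.505 to 71.6) lies within 20 Mb of it, against 3.85% of 3999 measured genes. Genes apart in fewer than 3 germ classes were not part of this count, so it does not bear on those named in single classes. App and Eva1c lie on chromosome 16, and of 80 measured genes between 50 and 95 Mb there, 12.5% (6.16 to 21.8) were at least 1.5-fold apart in late spermatocytes against 4.33% elsewhere. The shares are 13.1% (7.34 to 21.0) and 3.05% in round spermatids, 17.1% and 7.17% in spermatogonia and 16.7% and 3.71% in elongating spermatids, but 8.16% (2.27 to 19.6) and 7.44% in Sertoli cells, which would carry the same sequence. The interval in late spermatocytes reaches below 2 times the share elsewhere, the bound set for this test, so a strain difference there stays open beside the knockout, which was not tested apart from it.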

How the results depend on the processing

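The alternatives with at least 2000 UMIs, with mixed clusters named by their best class, with 1 lowest-decile barcode subtracted per cell and without the cell with most UMIs of a gene were chosen after seeing the data, and the others before. No paired analysis was possible because each genotype has 1 library, and for the same reason no replicate could be left out. Of 77 values for 7 shares under 11 alternatives, 55 stayed within the counting interval, 19 moved and 3 turned. Of 1458 values for 162 genes that the naming rule lets the text name, under 9 alternatives, 1349 stayed, 97 moved and 12 turned, and of 416 values for 52 list medians under 8, 342 stayed, 61 moved and 13 turned. Part of this agreement is built in. For shares, no doublet removal equals the main setting, and for genes, dropping the low-count filter changes nothing. TMM and median-of-ratios factors shift every gene of a class alike, so medians over matched lists can hardly move. Igf2bp1 in spermatogonia (−1.60) kept its direction under all 9, from −1.65 to −1.48, the low-count filter among them, which cannot change it. The lower germ cell share and the higher Sertoli and Leydig shares kept their direction under all 11, no doublet removal among them, which equals the main setting.

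Shares are log2 ratios, knockout over wild type. With mixed clusters named by their best class, the germ cell share was −1.71, spermatogonia with early spermatocytes 0.13, late spermatocytes 0.47 (turned), round spermatids −0.40, elongating spermatids −0.21 (turned), Sertoli 0.022 and Leydig 5.15. Naming each cell by its marker level gave −1.24 for germ cells, 0.21 for round spermatids, −0.15 for elongating spermatids (turned), 0.13 for Sertoli and 4.46 for Leydig. With at least 2000 UMIs they were −0.62 for germ cells, −0.65 for late spermatocytes, 0.28 for elongating spermatids and 2.31 for Sertoli, of which 7 wild type and 21 knockout cells were left. Without a barcode filter germ cells were −1.03 and round spermatids −0.19. Thinned to 1000 UMIs, late spermatocytes were −0.14 and round spermatids −0.29. Centring genes within library gave −0.64 for late spermatocytes, and resolution 0.5 gave 3.1 for Leydig.

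Among genes, leaving out the cell with most UMIs turned Afg3l1 (−0.22), Mirt1 (−1.17), Gfod2 (−0.048) and Ppm1k (2.57) in spermatogonia, which rest on that cell. The stricter filter turned Afg3l1 (−0.21) and Mirt1 (−1.11). Taking off 5% of the profile of all kept barcodes, which may remove more than free RNA, turned Insl3 in late spermatocytes (−1.37) and round spermatids (−2.84). Equal weights of clusters turned Tnp1 in round spermatids (0.19) and Myo15b (0.58) in elongating spermatids. TMM and median-of-ratios factors turned Tnp2 in elongating spermatids (−0.040 and −0.066), where they shift every gene.

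List medians are given over matched lists. Equal weights turned stem cell maintenance in spermatogonia (0.038) and, in elongating spermatids, flagellum (−0.017), heat shock (−0.23) and extracellular matrix (−0.038). Taking off 5% of the profile of all kept barcodes turned Sertoli support in round spermatids (−0.054). In elongating spermatids it turned antioxidant response (−0.0080), Sertoli support (−0.19) and extracellular matrix (−0.13). Subtracting 1 lowest-decile barcode per cell turned acrosome (−0.014) and flagellum (−0.11) in elongating spermatids and flagellum (−0.21) and immediate early genes (−0.47) in Sertoli cells. Without the low-count filter, extracellular matrix in spermatogonia turned (−0.059). Where no reason is given, the cause was not tested. Depth and cell number limit how many genes could be measured, 9136 in spermatogonia and 15172 in round spermatids.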

Other observations

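The knockout library holds immune cells that the wild type library nearly lacks, and part of its B lymphocytes carry genes of precursor cells. Of 349 such cells, 91.1% carry Ighm, the heavy chain of the first antibody class, 84.8% Vpreb3 and 86.5% Ebf1, a factor of early B cell identity. Vpreb1 and Igll1, the surrogate light chain of precursor cells, appear in 22.6% and 17.8%, and Rag1, which recombines antibody genes, in 8.88%. In 124 T or NK lymphocytes of the same library, which should lack them, Ighm appears in 7.26%, Ebf1 in 1.61%, Rag1 in 1.61%, Vpreb3 and Igll1 in 0.806% each and Vpreb1 in 0, at median depths of 2417 (B) and 2649.5 UMIs (T or NK). Over all kept barcodes Igkc has 1 UMI in wild type and 27000 in the knockout, while Hbb-bs, a haemoglobin gene of red cells, stands at 11.9 and 14.2 CPM. The wild type library in turn holds S100a8 (202 UMIs against 1) and S100a9 (249 against 0), genes of neutrophils and inflammatory monocytes, mostly in its macrophage class. These genes were chosen after their values were seen.

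Leydig cells (43 and 370) also differed in level, with genes outside the fixed rule chosen after values were seen. Insl3 stood at −0.76 (−0.79 to −0.73) on the log2 scale and Hsd3b1, an enzyme of steroid synthesis, at −0.78, while Cyp11a1, which starts steroid synthesis, stood at 0.80 and Lcn2 at 0.74. Star, the cholesterol carrier, stood at −0.23 and Cyp17a1 at 0.34. In macrophages (43 and 195) Il1b, an inflammatory cytokine, stood at −1.46, and Cd163, a marker of resident macrophages, had 1 and 48 UMIs. The wild type values rest on 43 cells of 1 library in each class, and the wild type macrophages also hold 186 S100a8 and 232 S100a9 UMIs against 0 in the knockout, so the class differs in more than Il1b.

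X-linked UMIs were 1.61% of UMIs in spermatogonia of both libraries, 1.23% and 1.51% in early spermatocytes, 0.210% and 0.229% in late spermatocytes, where the X is silenced, 0.930% and 0.986% in round spermatids and 1.01% and 1.11% in elongating spermatids. Y-linked UMIs were 0.0338% and 0.0364% in round spermatids and 0.00658% and 0.00826% in elongating spermatids. Mitochondrial UMIs were 0.468% and 0.626% in round and 0.266% and 0.397% in elongating spermatids (wild type and knockout). In the mixed cluster led by Leydig genes the median mitochondrial percent per barcode was 2.75% in the knockout, against a median of 7.84% in whole Leydig cells of the same library.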
